A study of Homo sapiens with 2 samples.

How the data were processed

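RNA levels were measured on 2 Affymetrix arrays, 1 for U87 MG cells grown with vehicle and 1 for U87 MG cells grown with 30 nM panobinostat for 3 weeks. U87 MG is an established human glioblastoma cell line. Panobinostat is a hydroxamate drug that inhibits the zinc-dependent histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. Per the labels' protocols, both RNAs were extracted at the same time with a column kit and labelled with biotin using the WT Plus kit.

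The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes they came from RMA, with the affy package version 1.36.1 and R version 2.15.1. RMA corrects background, quantile-normalizes probes and summarizes each probe set by median polish, so its log2 differences tend to understate large changes at low signal. The settings used, the arrays normalized together and any detection calls are not given in the sources used here. The table held 23786 probe sets, and the values ran from 0.467 to 12.5 on the vehicle array and from 0.393 to 12.3 on the panobinostat array. No gene centring was seen, since the column medians were 3.68 and 3.76. Scanner files were not used here.

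Probe sets were named through the platform annotation, and the Entrez number of each named probe set matched a gene of the RefSeq table used (GRCh38.p14), which served for gene type, chromosome and order of neighbours. Of the probe sets, 22458 had 1 gene symbol, 0 had several and 1328 had none in the annotation used here. Each named gene had 1 probe set, so the probe-set agreement planned as an error estimate, and the average over a gene's probe sets planned as an alternative, could not be computed. Exactly equal values on both arrays were found for 995 named genes. The 1320 that shared both values with a different probe set overlap with these, and their median vehicle level was 1.86, close to the floor. The annotation names no genome build for the probes, so no coordinates are given.

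For each gene the vehicle log2 value was subtracted from the panobinostat log2 value. With 1 array per group there was no residual error, no test and no p-value, and every difference is between these 2 arrays. Per the labels, cells were passaged at confluence, and their density at harvest is not given in the sources used here. Genes were counted as higher or lower when the difference was at least 1 in size, which is 2-fold. Having 1 array per group limits the precision, and the spread of 2 kinds of genes was used as a yardstick. It covers gene-to-gene variation, not replicate error. The 354 olfactory receptor genes, mostly near the floor at a median vehicle level of 1.80, had an SD of 0.51 in their log2 differences, and 5.37% of them were at least 2-fold apart. The 95th percentile of their levels, 3.12 with vehicle and 3.07 with panobinostat, was taken after the data were seen as the floor. A fold of a gene whose lower value lay under it is given as at least the ratio of its higher value to the floor, while log2 differences, medians and counts use the values as measured. The 41 measured members of the fixed ribosomal protein and oxidative phosphorylation lists had an SD of 0.40, and 0 of them were 2-fold apart. Wider families did hold such genes, with 2 higher and 1 lower among 41 RPL genes (median -0.30, percentile 1.85) and 2 higher and 2 lower among 30 RPS genes.

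Before the data were examined, 40 gene lists were fixed, with 786 distinct members, of which 712 had a named probe set. The other members are not analysed here. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on the mean of both arrays in 20 level bins. A percentile of at most 2.5 or at least 97.5 was called below or above random lists, which 2 of 40 lists would reach by construction. The percentile describes these 2 arrays, and members of a list are not independent. Chromosomes were treated alike with 10000 random sets each, and gene families, chosen later, with 2000. On simulated data made by shuffling the differences within level bins over the 22458 genes, 94.5% of lists of 20 genes with no shift were placed inside, 95% with a planted shift of 0.5 were placed above, and 100% with a planted shift of 1 were placed above. For lists of 10 genes these shares were 93%, 72% and 100%, so short lists placed inside can hold a shift of 0.5. The simulated lists were drawn from genes of all levels and placed among fewer than 10000 random lists. Random medians spread differently by level, for example from -0.44 to 0.29 for the 20 unfolded protein response genes. The shares therefore need not hold for the fixed lists, whose members often have higher levels.

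The genes named in the text follow a rule also fixed before the data were examined. They are the 10 highest and 10 lowest differences among genes whose higher value reached the median of that value (4.09), leaving out small RNAs, placeholder symbols and pseudogenes, every zinc-dependent histone deacetylase, and in each list the 2 highest and 2 lowest members, of which those with a difference under 1 in size may be left out. MKI67, CDKN1A, CCND1, MYC, MAGEC2, EGFR, VIM, SOX2, ABCB1, BCL2, MCL1, IL1B, B2M and EP300, the genes first named in the closing observations, and the relatives of named genes, were added after their values were seen. The alternatives planned were centring, a loess fit of the difference on the mean level with a span of 0.4, quantile normalization of both columns, a filter on low levels and random lists without matching. Restriction to protein-coding genes, removal of genes with equal or shared values, and filters on the mean of both arrays or on the vehicle level, were added after the data were seen. The planned filter keeps genes whose higher value is at or above the median of that value, so a gene can pass it by its difference. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.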

Results

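Gene expression was profiled in U87 MG glioblastoma cells kept for 3 weeks in medium with vehicle or with 30 nM panobinostat, to describe how long exposure to the histone deacetylase inhibitor altered the transcriptome. There were 2 arrays, 1 per condition, and none of the values below has a replicate. The arrays correlated across probe sets with a Pearson r of 0.941 and a Spearman rho of 0.942, where probe sets are not independent replicates. Of 22458 named genes, 1626 (7.24%) were at least 2-fold higher and 1402 (6.24%) at least 2-fold lower on the panobinostat array. In 587 of the former and 238 of the latter, the lower of both values lay under the floor set by olfactory receptors. The median difference of all named genes was 0 on the log2 scale, and its SD was 0.77. Large differences as measured leaned upward, since 39 genes were at least 16-fold higher and 9 were at least 16-fold lower. Most of the 39 had a vehicle value under the floor, whereas of the 9 only AQP9 and IFI44L had a panobinostat value under it. Against the floor some of the 39, such as EGLN3 (at least 6.55-fold) and FABP4 (at least 5.70-fold), need not reach 16-fold. The upward lean therefore rests largely on folds that are less certain.

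The 10 named genes with the highest differences had levels from 1.32 to 3.57 with vehicle and from 6.95 to 10.77 with panobinostat. All but SOST had a vehicle value under the floor, so their log2 differences as measured are less certain. Against the floor they ranged from at least 14.25-fold (LCE1F) to at least 201-fold (ACTBL2) higher. ACTBL2, a beta-actin-like gene, stood at 1.91 with vehicle and 10.77 with panobinostat, a log2 difference of 8.86. UCA1, a long noncoding RNA described in urothelial cancer, differed by 7.04, and KRTAP2-3, a hair keratin-associated protein, by 6.76. RFPL4AL1 differed by 6.17, the T-cell receptor segment TRBV20-1 by 6.01 and FXYD7, a regulator of the sodium pump, by 5.98. SOST, which encodes the Wnt antagonist sclerostin, differed by 5.71. LCE1F, a late cornified envelope gene, differed by 5.64, ENPP5 by 5.54 and SLN, the calcium pump regulator sarcolipin, by 5.53. Of the relatives set beside them, ACTG1 stood at 10.85 and 10.84, and KRTAP2-1, KRTAP2-2, KRTAP2-4, LCE1A, LCE1B, LCE1C and LCE1E stayed within 2-fold, at 2.53 or less with panobinostat. TRBV24-1, another T-cell receptor segment, differed by 4.08. Whether a probe set also binds transcripts of a close relative cannot be checked from the table.

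Of the 10 genes most below vehicle, KIF20A and PLK1 belong to the mitosis list and IFI44L to the interferon list. KIF20A, a kinesin of cytokinesis, was 27.8-fold lower. PLK1, the polo-like mitotic kinase, was 17.1-fold lower, and FOXM1, a transcription factor of G2 and M phase genes, was 15.8-fold lower. The histone genes H3C7, H2BC14, H1-5 and H3C8 were 17.3-fold, 17.3-fold, 17.2-fold and 16.1-fold lower, and such genes have close copies that probes can share. The remaining genes were AQP9, a water and glycerol channel, at -4.17 on the log2 scale, IFI44L, an interferon-stimulated gene, at least 11.4-fold lower, and PRRX1, a mesenchymal homeobox factor, 17.6-fold lower.

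**Figure D1:**
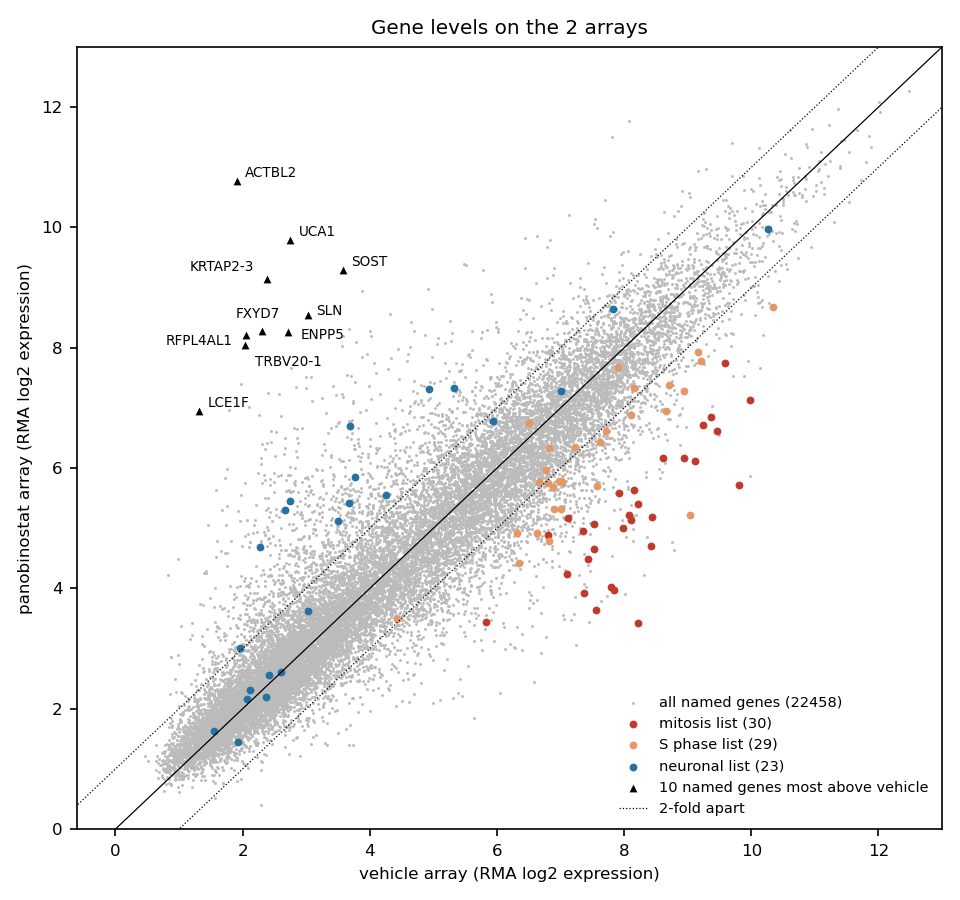
RMA log2 expression of 22458 named genes on the vehicle array (horizontal axis) and the panobinostat array (vertical axis), 1 array each, with dotted lines at 2-fold. The S phase list is orange and the neuronal list blue, all 30 mitosis genes (red) lie below the lower dotted line, and the 10 named genes with the highest differences (triangles) lie far above the upper one.

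Among the 40 gene lists, 10 had medians above their matched random lists, 6 had medians below them and 24 lay inside, where 2 outside would arise by construction.

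Every one of the 30 mitosis genes measured was at least 2-fold lower with panobinostat, and their median difference was -2.85, a 7.21-fold lower level. The middle of the list ran from -3.18 to -2.47 (quartiles), against a range of -0.40 to 0.23 for the medians of random lists (percentile 0). The members that differed least, TPX2 and TTK, a spindle assembly factor and a checkpoint kinase, were still 3.56-fold and 3.75-fold lower. MKI67, the gene of the proliferation antigen Ki-67, was 7.25-fold lower. DNA replication and S phase genes were lower by a smaller amount. Their median was -1.23 (percentile 0), with 21 of 29 members at least 2-fold lower and 0 at least 2-fold higher. TYMS, thymidylate synthase, was 14.2-fold lower and ORC1, of the origin recognition complex, 4.11-fold lower. CCNE1, cyclin E1, was at 0.25 and SLBP, which binds histone mRNA, at -0.22.

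The replication-dependent histone list split. Its median was -1.24 (percentile 0), and 6 of 12 members were at least 2-fold lower, among them H2AC4 (at least 5.91-fold, from 5.64 to 1.84) and H3C2 (at least 9.95-fold). On the other side H2BC8 was at least 5.68-fold and H2BC5 at least 3.30-fold higher. DNA repair genes had a median of -0.52 (percentile 0.41), and 8 of 24 were at least 2-fold lower. FANCI, of the Fanconi anaemia pathway, was 5.46-fold lower and BRCA1, of homologous recombination, 4.69-fold lower. LIG4 and MGMT, the latter at 2.73 with vehicle, were highest in the list at 0.33 and 0.26.

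Across the 11 zinc-dependent histone deacetylases the median was -0.12 (percentile 35.8), with 2 at least 2-fold higher and 1 lower. HDAC11 was 3.05-fold and HDAC3 2.59-fold higher, and HDAC7 was 2.90-fold lower. HDAC5 and HDAC8 had differences of 0.93 and 0.80, HDAC10, HDAC6 and HDAC9 of -0.81, -0.54 and -0.42, and the abundant HDAC1 and HDAC2 of -0.02 and -0.14, with HDAC4 at -0.12. Acetyltransferase and bromodomain genes had a median of -0.78, below random lists (percentile 0.16), with 5 of 15 at least 2-fold lower and 0 higher. KAT6B was 3.06-fold and CREBBP 2.76-fold lower, EP300 was at -0.78, and BRD7 and BRD3 were highest at 0.88 and -0.20.

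Genes known to be induced by deacetylase inhibitors had a median of 0.75 (percentile 99.98), and 5 of 16 were at least 2-fold higher and 0 lower. DHRS2, a short-chain dehydrogenase, was 22.1-fold higher and RHOB, a small GTPase, 8.05-fold higher. CDKN1A, which encodes the cell cycle inhibitor p21, differed by only 0.20. H2BC12 and MT1E were lowest in the list, at -0.96 and -0.67. The p53 target genes as a list lay inside random lists (median -0.07, mean 0.03, percentile 52.1). GDF15, a stress cytokine, was 7.40-fold and PLK3 2.70-fold higher, and FAS, a death receptor, was 2.57-fold lower.

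Neuronal genes had a median of 0.86, above random lists (percentile 100), with 11 of 23 at least 2-fold higher and 0 lower. SYP, synaptophysin, was 8.06-fold and SCG2, secretogranin II, at least 5.02-fold higher. NEFL and UCHL1 were lowest, at -0.47 and -0.29. Tubulin and microtubule genes went both ways, with 5 of 19 at least 2-fold higher and 4 lower, and a median (-0.28, percentile 11.4) opposite in sign to the mean (0.33). TUBB4A and MAP2, both typical of neurons, were at least 9.26-fold and 5.22-fold higher, while TUBA1C and STMN1 were 2.93-fold and 2.66-fold lower. The astrocyte list (median 0.15, percentile 86.4) and the oligodendrocyte list (median -0.05, mean 0.01, percentile 38.7) lay inside random lists. Without genes of equal or shared values the astrocyte median, over 12 members, was 0.55 and above random lists (percentile 99.57). It stayed inside among genes at or above the median level (0.42, percentile 92.53) or the median vehicle level (0.15, percentile 77.05). ALDOC and SOX9 were at 1.99 and 1.97, SLC1A3, a glutamate transporter, was 2.93-fold lower, OLIG2 was at least 2.63-fold higher, and GFAP stood at 3.36 with vehicle with a difference of -0.47. The neural stem cell list had a median of 0.26 (percentile 96.4). In it ITGA6, integrin alpha 6, was at least 18.7-fold and L1CAM, a neural adhesion molecule, at least 3.80-fold higher, LIF was 2.24-fold lower, ID3 was at -0.99, and SOX2 stayed near the floor at 2.23 with vehicle.

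Inflammatory cytokine and chemokine genes had a median of 0.78, above random lists (percentile 100), with 11 of 24 at least 2-fold higher and 2 lower. CCL20 was at least 21.1-fold, IL1A at least 16.0-fold and IL1B 6.04-fold higher, whereas CSF3, which encodes G-CSF, was 3.11-fold and LIF 2.24-fold lower. Interferon-stimulated genes went both ways and lay inside random lists (median -0.15, percentile 11.8). Of 33, 6 were at least 2-fold higher, led by IFI6 (5.05-fold) and OAS1 (4.50-fold), and 7 were lower, led by IFI44L and IFI44 (3.56-fold). Of the higher members BST2, IFIH1 and IFIT1 had vehicle values under the floor, and IFIT1 stayed under it on both arrays. Among members at or above the median level the median was -0.42 (percentile 3.94). Among those at or above the median vehicle level it was -0.50 (percentile 2.96). Both were lower but still inside random lists. The MHC class I list had a median of -0.49, below random lists (percentile 2.10), and 4 of 15 members were at least 2-fold lower. The members that differed most were PSMB10, an immunoproteasome subunit (4.08-fold lower), and ERAP1, a peptide-trimming enzyme (3.74-fold lower). HLA-B was at 0.65, HLA-C at 0.51 and B2M at -0.15. Removing genes of equal or shared values moved this list inside random lists (percentile 2.78).

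Glycolysis and hypoxia genes had a median of 0.75 (percentile 100), with 10 of 25 at least 2-fold higher. EGLN3, a HIF prolyl hydroxylase, was at least 6.55-fold higher (from 1.73 to 5.83) and ANGPTL4 10.3-fold higher, while VEGFA was 3.14-fold lower and ENO1 was at -0.40. Oxidative phosphorylation genes showed no 2-fold difference in 23 members (median -0.07, percentile 50.3). Their extremes were NDUFA9 and CYC1 at -0.91 and -0.86 and COX6C and UQCRC1 at 0.62 and 0.56. The cholesterol list had a median of 0.53 (percentile 99.59), led by DHCR7 (3.78-fold) and STARD4 (3.29-fold), with CYP51A1 (2.42-fold) and INSIG1 (2.15-fold) lower.

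The NRF2 and oxidative stress list had a median of 0.37 (percentile 99.62), led by AKR1B10 (5.16-fold) and AKR1C3 (3.17-fold), with GPX1 2.35-fold lower and TKT at -0.85. The unfolded protein response list had a median of 0.33 (percentile 98.4), led by ATF3 and SDF2L1 (2.46-fold and 2.10-fold), with PPP1R15A and XBP1 2.47-fold and 2.08-fold lower. Metallothioneins had a median of 0.70 (percentile 99.89) but went apart, with MT1G 6.15-fold and MT3 4.09-fold higher and MT1M 11.1-fold lower. The metallothionein median was 0.24 (percentile 87.6), and the NRF2 median 0.28 (percentile 97.07), among genes at or above the median level, both inside random lists. Heat shock proteins (median 0.07, percentile 75.9) lay inside random lists, although HSPA2 was 16.7-fold and CRYAB, alpha B crystallin, at least 2.38-fold higher (from 1.76 to 4.37), with HSPD1 2.10-fold lower. In the autophagy and lysosome list (median 0.17, mean -0.03, percentile 92.3) GABARAPL2 was 2.49-fold and MAP1LC3B 2.03-fold higher, and the cathepsins CTSS and CTSL were at least 7.87-fold and 2.45-fold lower.

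The matrix protease list held members far apart in both directions, so its median of 0.54 (percentile 99.94) describes few of its members. MMP1, interstitial collagenase, was 33.7-fold and PLAT, tissue plasminogen activator, 14.6-fold higher. ADAMTS5 and ADAMTS1, aggrecanases, were at -3.56 and -3.17. In all, 8 of 18 members were at least 2-fold higher and 6 lower. Among members at or above the median vehicle level the median was -0.02 (percentile 59.6), inside random lists. TGF-beta and SMAD targets had a median of 0.40 (percentile 99.2), 7 of 18 at least 2-fold higher and 0 lower, led by BAMBI (15.0-fold) and CCN2 (10.4-fold). Without genes below the median level this list's median was 0.29 (percentile 96.61), inside random lists. Collagens (median 0.05, mean -0.14, percentile 74.9) lay inside, with a median of the other sign (-0.28) among genes at or above the median level, and with COL1A1 3.41-fold and COL1A2 2.45-fold lower and COL8A1 2.10-fold higher. Mesenchymal genes (median 0.04, percentile 69.3) also did, with THY1 6.77-fold and SNAI1 4.14-fold higher, TAGLN from 3.41 to 2.39, and VIM, vimentin, at -0.10.

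Growth factor receptors lay inside random lists (median 0.03, percentile 68.1), and 6 of 28 were at least 2-fold higher. PDGFRA was at least 7.44-fold and MERTK at least 2.92-fold higher, DDR2 was 2.90-fold and AXL 2.63-fold lower, and EGFR was at -0.50. Among drug efflux transporters (median 0.36, percentile 95.2) ABCG2 was 2.69-fold and ABCC3 2.12-fold higher, ABCC2 and ABCC4 were 2.38-fold and 2.26-fold lower, and ABCB1 was at 0.43 from a vehicle level of 2.46. Anti-apoptotic genes had a median of -0.50 (percentile 4.07), with BIRC5, survivin and also a mitosis list member, 10.9-fold lower, BIRC2 at -1.48, BCL2A1 at least 1.74-fold higher, BCL2 at -0.50 and MCL1 at -0.40. Among pro-apoptotic genes (median -0.23, mean 0.11, percentile 15.1) PMAIP1, which encodes NOXA, was 4.57-fold and BCL2L11, which encodes BIM, 3.00-fold higher, and FAS was 2.57-fold lower. Wnt and Notch targets had a median of 0.22 (percentile 94.5), with the antagonists DKK1 7.33-fold and DKK3 5.07-fold higher and LEF1 2.64-fold and WNT5A 2.03-fold lower. Immediate early genes had a median of 0.25 (percentile 97.3), with DUSP5 5.29-fold and DUSP1 3.06-fold higher, FOSL1 3.92-fold, EGR1 2.11-fold and CCND1 2.09-fold lower, and MYC at 0.25. Of 17 cancer-testis antigens (median 0.01, percentile 56.7), 3 were at least 2-fold higher and 0 lower, namely SSX1 (at least 4.51-fold), MAGEC1 (at least 2.85-fold) and MAGEC2 (3.41-fold).

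Markers of other cell types gave no list outside the random range over all named genes. The epithelial list had a median of 0.18 (percentile 86.5), with KRT8 3.01-fold higher, and KRT5 and KRT14 at -0.47 and -0.31. OCLN in this list went from 1.36, under the vehicle floor, to 3.08, barely above the panobinostat floor of 3.07. The 4 epithelial members at or above the median vehicle level had a median of 0.78, above random lists (percentile 99.8). Endothelial genes had a median of -0.13 (percentile 17.3), with 0 of 10 members 2-fold apart. Macrophage and leukocyte genes had a median of 0 (percentile 42.2), with CSF1R 2.41-fold lower. Fibroblast and pericyte genes had a median of 0.36 (percentile 96.2), with PDGFRA and THY1 higher and FAP (5.19-fold) and COL1A1 lower. Cytosolic ribosomal proteins, used by every cell, had a median of -0.26 (percentile 11.9), with 0 of 18 members 2-fold apart.

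**Figure D2:**
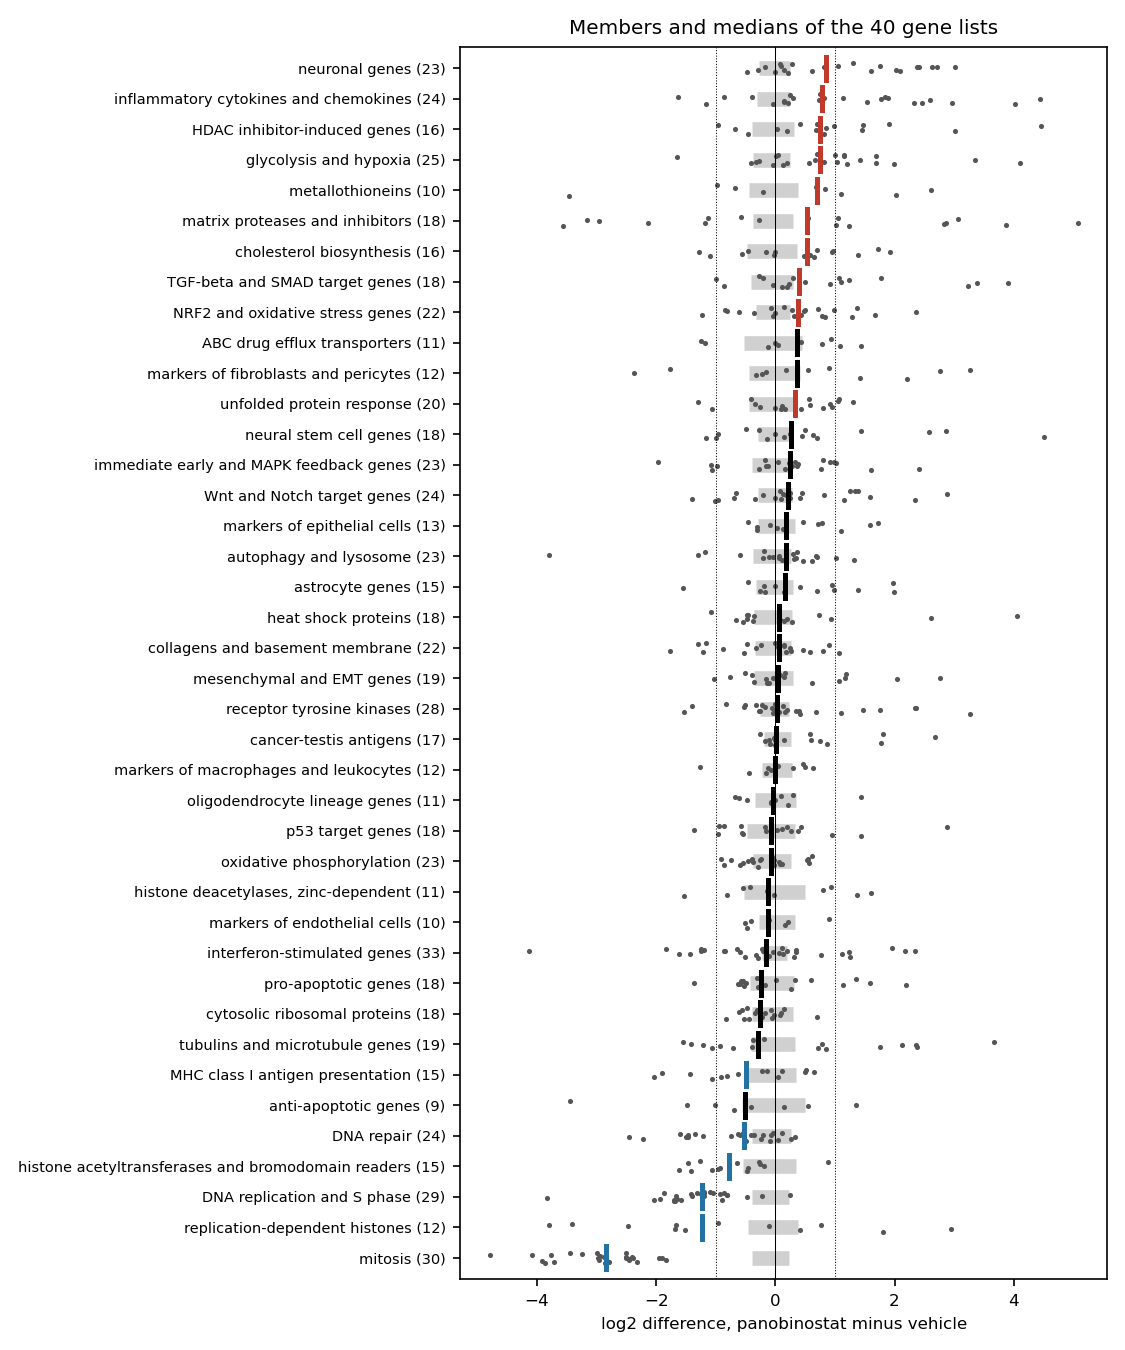
Log2 difference, panobinostat minus vehicle, of each member (points) of the 40 gene lists, with the number of members measured in brackets. Vertical bars are list medians, red above and blue below the middle 95% of medians of matched random lists (grey), black inside, and the mitosis list stands apart at -2.85.

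Gene differences were also summarised by chromosome. Over all named genes, chromosome 14 had the highest median, 0.09 over 916 genes (percentile 100), and chromosome 4 followed with 0.07 over 851 (percentile 100). Chromosome 16 had the lowest, -0.11 over 884 (percentile 0). Of 23 chromosomes, 3 lay above random sets (4, 14 and 15) and 4 below (6, 11, 12 and 16), where 1.15 would arise by construction. Among the 11229 genes at or above the median level, a restriction chosen after the values were seen, the median of all was -0.06. There chromosome 14 was at 0.14 over 384 genes, with 56 at least 2-fold higher and 23 lower, chromosome 4 at 0.10 over 416, and chromosomes 12 and 16 both at -0.21. In that restriction chromosomes 6 and 15 lay inside random sets (percentiles 19.8 and 71.7) and chromosome 1 lay above them (percentile 99.89). When the mean of both arrays set the level instead, chromosome 14 was at 0.13 over 387 genes, and chromosome 9 lay below random sets too (percentile 2.02).

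**Figure D3:**
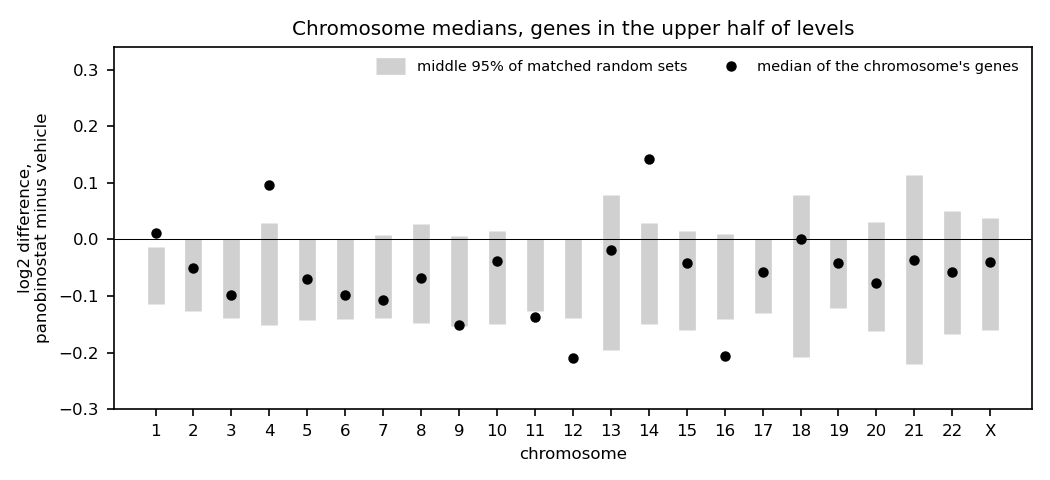
Median log2 difference, panobinostat minus vehicle, of the genes at or above the median level on each chromosome (points), against the middle 95% of level-matched random gene sets (grey bars). Chromosomes 1, 4 and 14 lie above the bars, and 11, 12 and 16 below.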

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

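Probe sets with no gene symbol in the annotation used here enter none of the comparisons above. Of 1328 such probe sets, 77 (5.80%) were at least 2-fold higher with panobinostat than with vehicle and 47 (3.54%) were at least 2-fold lower. These shares are below the 7.24% and 6.24% of named genes. The probe sets are given because they are data outside the main measurement, no replicate measures their error, and their identity was not examined.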

How the results depend on the processing

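The counts of 1626 genes at least 2-fold higher and 1402 lower, and of 16 lists outside random lists, stayed within 1.5 times under each alternative run, except that 804 genes were higher among those at or above the median vehicle level. No named gene at least 2-fold apart changed sign, but none could, since the settings moved single genes by at most 0.21. Of lists outside random lists 1 changed sign, the matrix proteases (-0.023 among genes at or above the median vehicle level). Smaller values changed sign too: HDAC1 was at 0.06 under loess and 0.03 under quantile normalization, the p53 list at 0.03 and 0.01, the mesenchymal list at -0.01 under quantile normalization and the collagen list at -0.28 among genes whose higher value reached its median. Centring moved nothing, since the median difference was already 0, and so tests nothing. Loess moved single genes by at most 0.12 and quantile normalization by at most 0.21. The median of all genes moved by less than 0.1 under both. The average over a gene's probe sets was not run, because each gene had 1. Under quantile normalization the anti-apoptotic list (-0.59) and the neural stem cell list (0.28) went outside random lists. Under loess the immediate early list (0.34) did. With random lists not matched on level, the medians of the anti-apoptotic (-0.50), efflux transporter (0.36), immediate early (0.25) and fibroblast (0.36) lists went outside. Among genes whose higher value reached its median, the metallothionein (0.24), NRF2 (0.28) and TGF-beta (0.29) lists went inside. The cancer-testis (1.79, 4 members) and Wnt and Notch (0.63) lists went outside there, which says little, since SSX1, MAGEC1, AXIN2, HEY1 and FZD7 passed this filter by their panobinostat values. A filter on the mean of both arrays, chosen after seeing the data, gave the same crossings (1.77 for 3 cancer-testis members) and has this fault too. A filter on the vehicle value, also chosen after seeing the data, leaves out such genes by construction, and the median of all genes was -0.14 under it. There the Wnt and Notch list stayed inside (0.14, percentile 91.2), the metallothionein (0.24), NRF2 (0.22) and TGF-beta (0.23) lists were inside, the epithelial list (0.78, 4 members) went outside, and the mesenchymal (-0.0013), collagen (-0.24), growth factor receptor (-0.10), neural stem cell (-0.28) and fibroblast (-0.16) medians changed sign. With genes of equal or shared values left out, an alternative chosen after seeing the data, the astrocyte (0.55) and immediate early (0.26) lists went outside and the MHC class I list (-0.49) went inside. Fewer genes enter the level filters and this setting by construction, and the cause of the other moves was not tested. Restriction to protein-coding genes, also chosen after seeing the data, moved no list across. EGR1, HSPD1, WNT5A and XBP1 came just short of 2-fold under loess, the last 3 of them also under quantile normalization, and HDAC5 passed it under loess. No paired analysis was possible because there was 1 array per condition, and none could be left out. Signal over background is unknown without detection calls, so differences among genes near the floor are the least certain.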

Other observations

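The tests in this part, and the rules for reading them, were chosen after the patterns they weigh were seen. The loess setting and the S phase, immediate early and epithelial lists were fixed beforehand, but not as tests of these patterns. Beyond the fixed list, 55 genes of the replication-dependent histone clusters were measured. Of these, 30 were at least 2-fold lower with panobinostat and 3 were at least 2-fold higher, with a median of -1.28. The 3 were all H2B genes, H2BC8 (2.95), H2BC5 (1.80) and H2BC18 (1.79), while other H2B genes, such as H2BC14 (-4.11) and H2BC6 (-2.95), were among the lowest. Families of protein-coding genes sharing a symbol stem were screened next, and 38 of 327 lay outside their random sets (23 above and 15 below, where 16.4 would arise by construction). Nuclear pore genes had a median of -0.59 over 23, below random sets, with 5 at least 2-fold lower, among them NUP35 (-1.70) and NUP188 (-1.48). The medians of DEAD-box helicase genes (-0.49 over 36) and SR splicing factor genes (-0.60 over 12) were also below random sets, with 6 and 2 of these genes at least 2-fold lower.

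On the higher side, clustered protocadherin beta genes, neighbours that encode neuronal adhesion molecules, had a median of 0.96 over 16, with 8 at least 2-fold higher and 0 lower. PCDHB6 (2.60), PCDHB10 (2.55), PCDHB8 (2.34) and PCDHB2 (2.28) led, from vehicle levels between 1.38 and 3.05, all under the floor. These genes are similar in sequence. Against the floor PCDHB8 was at least 1.52-fold higher, and PCDHB3 (from 1.89 to 2.97) stayed under it on both arrays. Both are among the 8. The PCDHA genes (median 0 over 13) and PCDHGA genes (median 0.04 over 12) lay inside random sets, with 0 at least 2-fold apart. Tetraspanin genes had a median of 0.70 over 22, with 9 at least 2-fold higher and 0 lower, led by TSPAN7 (4.28), TSPAN15 (3.61) and TSPAN13 (2.37). Of 7 insulin-like growth factor binding protein genes, too few for the families screened (at least 8), IGFBP3 (2.10), IGFBP5 (1.95), IGFBP4 (1.65) and IGFBP2 (1.47) were higher, IGFBP6 (-1.19) and IGFBP1 (-1.05) were lower and IGFBP7 was at 0.48.

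The first pattern weighed was the lower level of all 30 mitosis genes. A level-dependent scaling difference between the arrays is argued against by random lists of like level, with medians mostly from -0.40 to 0.23. The median was -2.77 after the loess trend was subtracted, which adds little, since loess moved single genes by at most 0.12. A general loss of short-lived transcripts was not seen in the immediate early list, whose median was 0.25, above 0. Of its 23 members, 3 were at least 2-fold higher and 3 lower. The level of these genes also depends on their transcription, so the list cannot decide, and such a loss stays open. Fewer dividing cells at harvest is a candidate explanation that the S phase list goes with, as 21 of its 29 members were at least 2-fold lower. Whether the drug or the density of the cultures at harvest would have lowered division stays open, as does any difference particular to these 2 cultures.

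The second pattern was a group of 38 genes with a level under 3 with vehicle and at least 6 with panobinostat, against 5 the other way (39 and 7 after quantile normalization). Of 354 olfactory receptors, 8 were at least 2-fold higher and 11 lower, and of 17 cancer-testis antigens 3 were higher and 0 lower. These counts use the 2-fold cut, not the level cuts of this pattern. The olfactory receptor OR7C1 (from 2.38 to 6.41) was itself among the 38. Epithelial cells mixed into the culture stay open, because the 13 epithelial markers did not decide. Of them 3 were at least 2-fold higher, OCLN (1.72), KRT8 (1.59) and CLDN7 (1.10), and 0 were at least 2-fold lower. KRT5 (-0.47), KRT14 (-0.31) and EPCAM (-0.30) were below vehicle by less than 2-fold. The median was 0.18, inside random lists, and 0.78 for the 4 at or above the median vehicle level, above random lists. The epithelial genes CLDN1, KRT20 and PKP2 were among the 38. Probe noise near the floor, effects of the drug on silent genes, and a difference particular to these cultures, were not tested.

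The third pattern was the small upward shift of chromosome 14, picked from 23 chromosomes and weighed among genes at or above the median level. It was not removed by leaving out its most shifted stretch of 40 neighbouring genes (median 0.12, percentile 99.99). A median over 384 genes moves little when 40 are left out, so this weighs little against a single gene cluster as the cause. A scaling difference beyond the level matching of the random sets, more copies of the chromosome in the panobinostat culture, and regulation of many of its genes by the drug, stay open and were not tested. DNA was not measured here.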
